A study of Mus musculus with 8 samples.

How the data were processed

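RNA was measured in bone marrow-derived macrophages, cells grown from mouse bone marrow, of the C57BL/6 strain. There were 4 untreated libraries and 4 libraries from cells treated with interleukin-4 (IL-4), a cytokine of type 2 immunity. The series design calls the 4 samples of each group biological replicates, and the labels used here do not say whether each came from a different animal, so p-values measure the spread between these samples. Per the labels' protocols, total RNA was treated with DNase, depleted of ribosomal RNA and made into libraries by the TruSeq RNA procedure from the fragmentation step on. The submitters' processing notes name the genome build mm9 and the tools CASAVA 1.8.2, TopHat2 2.0.9, Cufflinks 2.1.1 and HTSeq, without their settings. The counter's handling of strand and of reads that meet several loci is not given in the sources used here.

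The authors deposited whole-number read counts for 31020 merged loci, of which 9940 had 0 counts in all libraries. They also deposited FPKM values, fragments per kilobase of transcript scaled to the mapped fragments of the library, for 89208 transcripts. The authors' merged annotation holds 89219 transcripts, assembled and reference ones together, with a code for how each relates to its nearest reference transcript. All value columns were matched to a library by the code in its label, and 0 were left over. The total count per library ran from 23071022 to 27783417. A group of 4 libraries with 0 counts still allows 3 counts in the group, and folds against such a group were computed against that floor and are given as lower bounds. Folds against 1 to 3 counts have exact binomial intervals at the 95% level. Floors and intervals cover counting error only. For FPKM the depth behind a single value is unknown.

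The files do not pair their locus and transcript IDs with gene names, and 0 of the IDs occurred in the reference tables at hand. The 34 gene lists with 790 symbols that were fixed before the data were examined matched 0 IDs, so the list tests and the parts of the naming rule that need symbols were not run. Loci are therefore given by their mm9 position, class and exon number. A locus was called protein-coding where a transcript of it carries a coding-sequence identifier in the merged annotation, and annotated non-coding where it holds reference transcripts and none does. Pseudogenes could not be set apart. Non-coding loci with under 200 exonic nucleotides (nt) were set apart as small. Loci without a reference transcript were called unannotated and split into intergenic, intronic and antisense by the authors' codes. Some 567 loci, 552 of them tested, join reference transcripts that do not overlap each other, and a value of such a locus may stand for several genes.

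Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the default expression filter (13761 loci kept) and the quasi-likelihood test of IL-4 against untreated, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Levels are CPM, the count of a locus scaled to the total count of its library. The standard error (SE) of a log2 fold change was derived from the test's F value. FPKM were tested with limma 3.58.1 on log2(FPKM + 0.1), with a variance trend, for isoforms at FPKM of at least 1 in at least 4 libraries; folds on that scale understate the change of low isoforms. Isoform use, meaning whether isoforms of a locus moved apart, was tested with limma's diffSplice and a Simes p per locus. Locus classes were tested as sets with camera at a preset correlation of 0.01, with an estimated correlation and with fry, a choice made after the data were seen. Shares of counts were compared by two-sided exact permutation tests, whose smallest possible p with 4 against 4 is 0.02857, and within the 4 replicate pairs, where it is 0.125.

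Each procedure was tested on simulated data built from the libraries' means, sizes and spread, with 200 changed loci or isoforms. Means came from the untreated libraries. Counts were drawn with a common dispersion for all loci, and isoform values with the spread of each isoform. Rises and falls were equal in number, and no pairing was simulated. Far more loci were called in the real data, so the recovered shares and false calls need not hold there. For the edgeR test, 65.67% of 1.5-fold, 88.06% of 2-fold and 93.94% of 4-fold changes among 13273 loci were recovered, with 9 false calls. For the limma isoform test on 16306 isoforms the shares were 50.75%, 64.18% and 93.94%, with 5 false calls. Of the changed isoforms at loci with several kept isoforms, diffSplice recovered 25%, 46% and 92.68% among 3770 loci with 39 false calls, more than the threshold allows. A log2 ratio of each isoform to the rest of its locus, added for that reason, recovered 8.333%, 32% and 90.24% with 2 false calls.

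The rule for named loci, fixed before the data were examined, took the 12 largest rises and the 12 largest falls, by fitted log2 fold change, past the threshold with a mean of at least 1 CPM and no overlap between groups. It also took 6 rises and 6 falls among annotated non-coding loci under the same conditions, 5 rises and 5 falls among unannotated multi-exon transcripts, and the 6 loci with the smallest Simes p. Loci among the 15 with the highest mean CPM are named besides, chosen after their values were seen. Alternatives were RLE and upper-quartile factors, no filter, a filter of 1 CPM and 10 counts in 4 libraries, DESeq2 1.42.0, limma-voom, edgeR's glmTreat against a 1.5-fold change, pseudocounts of 1 and 0.01, FPKM of at least 5, quantile normalization, a replicate block and leaving out each library. Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 served for annotation, neighbour tests and plots.

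Both groups carry replicate numbers 1 to 4. After subtraction of the group means, libraries of the same number correlated across loci at 0.3895, 0.1495, 0.2276 and 0.1788 for replicates 1 to 4. Libraries of different numbers correlated at -0.2677 to 0.2605. Untreated replicate 3 lay closer to IL-4 replicate 2 (0.2605) than to its own number, and values over 0.1 also occurred between untreated replicate 2 and IL-4 replicate 3 (0.1327) and between untreated replicate 1 and IL-4 replicate 4 (0.1226). Because all same-number values exceeded 0.1 the numbers were taken to pair the libraries, although the values separate the numbers only in part. The pairing comes from the data, since the labels state no shared animal or day. All main tests of loci, isoforms and isoform use fitted treatment only, without a replicate block, so their calls ignore this pairing. The replicate block is given as an alternative. For each locus the share of exonic nt also covered by exons of another locus was computed, because counts of such loci fell short of their FPKM. Reads of overlapping and antisense loci cannot be told apart without knowledge of strand, and 2590 of the tested loci share over 10% of their exonic nt with another locus.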

Results

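The transcriptome of mouse bone marrow-derived macrophages was compared between 4 untreated libraries and 4 libraries from IL-4-treated cells. The comparison asks which transcripts, coding and non-coding, differ in abundance after IL-4. Total counts per library ran from 23071022 to 27783417, and between 17767 and 18661 loci had reads in a library. Loci are named by mm9 position because the files do not pair their IDs with gene names.

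Treatment with IL-4 changed the abundance of 7127 of 13761 tested loci, of which 3524 rose and 3603 fell (edgeR without a replicate block, adjusted p under 0.05). With the block 7965 changed, but the counts that follow are without it. Changes of 2-fold or more were found for 1105 loci that rose and 1106 that fell. Changes of 10-fold or more were found for 268 loci that rose and 92 that fell. These 4 numbers were the same with the 27 loci that had a group at 0 counts set at the bound of their fold. Tested against a change of 1.5-fold, 1241 loci rose and 1226 fell (edgeR's glmTreat). The libraries of the 2 groups did not overlap at 6905 tested loci (2.857% would do so by chance). Of 10797 protein-coding loci, 2953 rose and 2915 fell, against 952 and 927 with glmTreat.

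**Figure D1:**
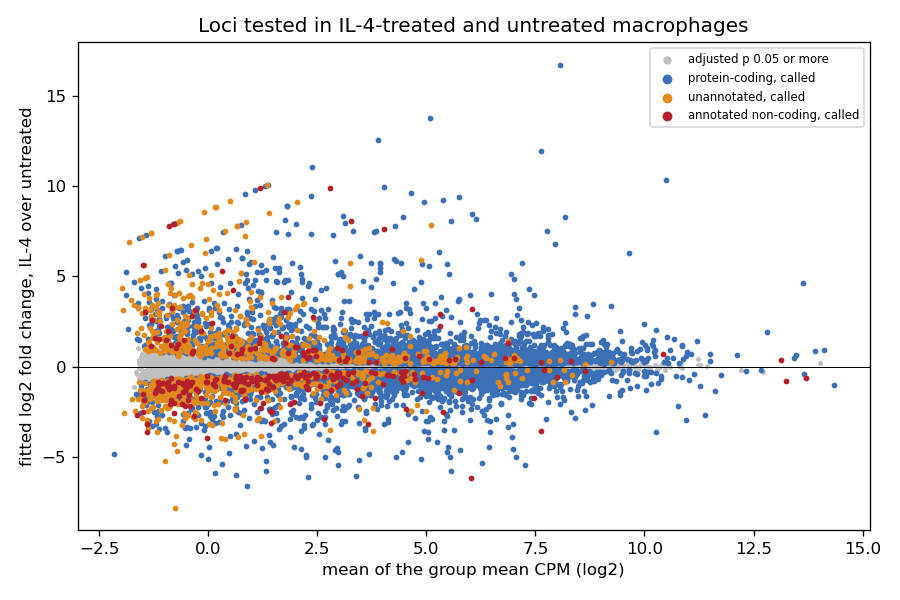
Each point is a tested locus, with the mean of the group mean CPM (log2) on the horizontal axis and the fitted log2 fold change of IL-4 over untreated, from 4 libraries per group, on the vertical axis. Coloured points are the loci past the adjusted p threshold in the classes of the legend, and very large rises (268 loci at 10-fold or more) outnumber very large falls (92 loci). The fitted values of loci with 0 counts in a group (27 loci) are no measured folds.

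The largest rises were ordered by fitted values, and loci with 0 untreated counts have only a lower bound, so their order is not measured. The highest bound was at the 4-exon protein-coding locus XLOC_010303 on chromosome 16 (48842665 to 48844574). It had 0 counts in the untreated libraries and 55407 counts, or 532 ± 92.5 CPM (SD, n = 4), with IL-4, at least 17390-fold higher (edgeR, adjusted p = 1.026e-08). A 17-exon protein-coding locus on chromosome 3 (55046448 to 55343086) went from 0 to 7107 counts, at least 2230-fold higher. At a 3-exon protein-coding locus on chromosome 7 (147232056 to 147238416) the group count went from 0 to 3091, at least 970-fold higher. A protein-coding locus with 12 exons on the X chromosome (130442965 to 130466989) went from 0 to 1087 counts, at least 341-fold higher. The 2-exon protein-coding locus on chromosome 14 (44680319 to 44681196) rose from 0.102 ± 0.0719 to 396 ± 130 CPM, a log2 fold change of 11.96 (SE 0.41, edgeR, adjusted p = 4.303e-09).

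The most abundant of the 12 loci with the largest fitted rises was XLOC_018018 on chromosome 3 (105945169 to 106152545), a protein-coding locus that joins 2 separate groups of reference transcripts. It rose from 2.32 ± 0.805 to 2894 ± 271 CPM, a log2 fold change of 10.38 (SE 0.20, edgeR, adjusted p = 1.068e-10). On the same chromosome a protein-coding locus of 8 exons (105255018 to 105477130) went from 3 to 3429 counts, a ratio of 1076 with an interval of 367.9 to 5220, and 2354 (422.2 to 93000) without untreated replicate 2. Protein-coding loci on chromosome 13 (42396639 to 42403358) and chromosome 19 (38191110 to 38199811) went from 0 counts to 540 and 514 counts, at least 169.5-fold and 161.3-fold higher. An unannotated single-exon locus on chromosome 10 (9985765 to 9989587) went from 0 to 528 counts, at least 165.7-fold higher. The other 2 of the 12 were annotated non-coding and are described with that class.

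The largest fitted fall was at XLOC_012748, a 12-exon protein-coding locus on chromosome 18 (52927465 to 53075767). It went from 358 counts in the untreated group to 3 with IL-4, a ratio of 0.00789 with an interval of 0.00162 to 0.0232, and 0.00355 (8.95e-05 to 0.0199) without IL-4 replicate 4 or 0.00342 (8.63e-05 to 0.0192) without both replicate 4 libraries. It was no longer the largest fitted fall without IL-4 replicate 1, IL-4 replicate 4 or both replicate 4 libraries. A protein-coding locus of 6 exons on chromosome 3 (96085957 to 96098013) fell from 299 ± 43.1 to 6.24 ± 1.56 CPM, 44.4-fold lower (edgeR, adjusted p = 3.951e-09). A 4-exon protein-coding locus on chromosome 1 (173103395 to 173127166) fell from 150.2 ± 7.57 to 3.33 ± 1.42 CPM, 41.6-fold lower. Neighbouring 2-exon protein-coding loci on chromosome 19 fell together. The locus at 34657821 to 34663472 fell from 93.0 ± 33.1 to 1.56 ± 0.345 CPM, and the locus at 34682423 to 34687891 from 9.56 ± 3.79 to 0.125 ± 0.128 CPM, 55.3-fold and 69.2-fold lower, the latter 129.1-fold without IL-4 replicate 1. Another locus on chromosome 1 (175496313 to 175529426), with 2 groups of reference transcripts, fell from 20.6 ± 12.01 to 0.274 ± 0.102 CPM. Protein-coding loci on chromosomes 18 (60535683 to 60552283), 11 (119400033 to 119409134), 13 (24419289 to 24569154) and 5 (92775667 to 92777880) fell 66.1-fold, 56.0-fold, 44.4-fold and 43.3-fold. Of these, the chromosome 18 locus had all its IL-4 counts in replicate 4 and was at least 79.0-fold lower without that library. The ratio was 0.00517 (0.000624 to 0.0188) on chromosome 11 without IL-4 replicate 1 and 0.0105 (0.00127 to 0.0385) on chromosome 5 without IL-4 replicate 4. A locus on chromosome 15 (30102348 to 30959098) went from 215 to 3 counts, a ratio of 0.0131 (0.00269 to 0.0389).

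**Figure D2:**
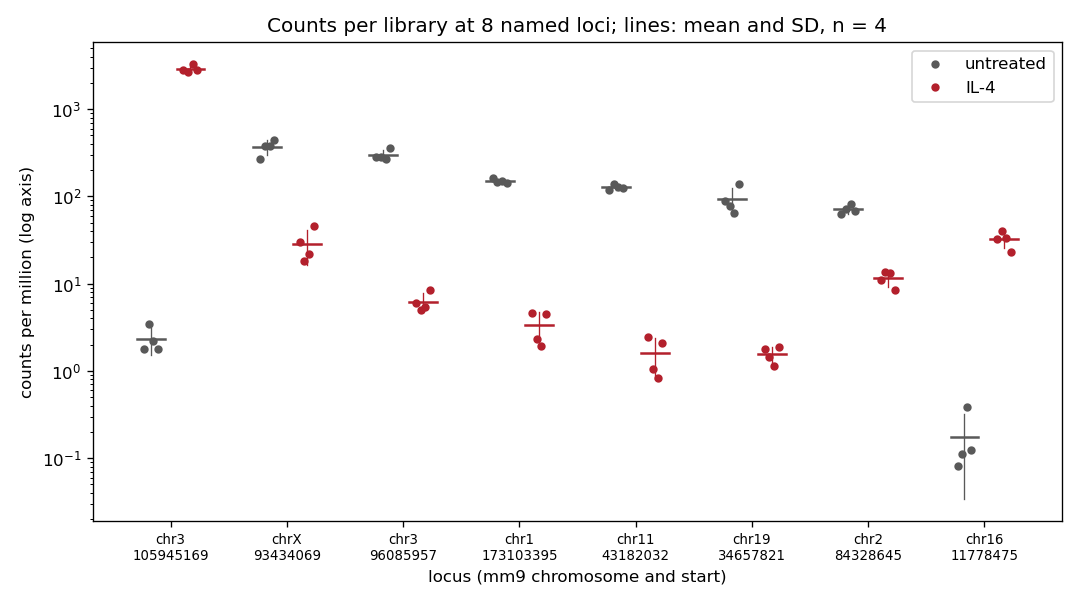
CPM per library on a log axis for the 8 most abundant loci with reads in every library among those named by rule for rises, falls and the non-coding class, each given by chromosome and start. Points are the 4 libraries of a group, horizontal lines the mean and vertical lines the SD. The rule took only loci without overlap between groups, so that the groups lie apart was set by selection.

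Among the most abundant loci, which were chosen after their values were seen, the largest change was on chromosome 9 (7344397 to 7369499). This 11-exon protein-coding locus rose from 1047 ± 274 to 24515 ± 4488 CPM, 25.2-fold (edgeR, adjusted p = 4.651e-08). A 16-exon protein-coding locus on chromosome 5 (17287508 to 17394777) rose 3.73-fold, from 3242 ± 903 to 11183 ± 941 CPM. Loci on chromosome 10 (59738875 to 59765348) and chromosome 6 (48983071 to 49038130) rose 1.86-fold and 1.79-fold. The locus with the highest untreated level, on chromosome 10 (116714413 to 116729968), fell from 28484 ± 5508 to 12900 ± 3443 CPM, a log2 fold change of -1.04 (SE 0.20). Calls at 6 of the others changed when a single library was left out, among them those on chromosomes 7, 14 and 4. The locus on chromosome 7 (149561821 to 149585774) went from 15215 ± 2026 to 10651 ± 2303 CPM (edgeR, adjusted p = 0.04945), and the call was lost when any library but IL-4 replicate 4 was left out (adjusted p = 0.05631 to 0.1505), with RLE or upper-quartile factors (0.06006 and 0.05025), without a filter on counts (0.05771) and with glmTreat. The locus on chromosome 14 (63740803 to 63797946), with 83.6% of its exonic nt shared, had 16202 ± 1428 and 16924 ± 1483 CPM (edgeR, adjusted p = 0.1958, and 0.04949 without untreated replicate 1). A 275-nt non-coding locus on chromosome 4 (43505657 to 43505931) had 7736 ± 235 and 5799 ± 1715 CPM (edgeR, adjusted p = 0.1196, 0.0005367 without IL-4 replicate 1, and 0.0288 with the replicate block). The 10 most abundant loci of each library together took 14.1% ± 0.896 of the counts in untreated and 15.5% ± 0.481 in IL-4 libraries (exact permutation p = 0.02857, adjusted over 10 shares 0.04081, higher with IL-4 in all 4 replicate pairs). That rise of 1.38 percentage points is smaller than the gain of the chromosome 9 locus alone, from 0.105% to 2.45% of the counts.

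The series was also typed as non-coding RNA profiling, and non-coding loci were counted apart. Of 661 tested annotated non-coding loci, 82 rose and 190 fell, with a median log2 fold change of -0.22. Without a filter on counts 127 rose and 214 fell of 1822. Tested against a change of 1.5-fold, 39 rose and 72 fell (edgeR's glmTreat). Adjusted over the class alone, 265 changed. As a set compared with the other loci, the class did not pass the test (limma's camera, adjusted p = 0.2967, and adjusted p = 0.9614 with an estimated correlation), nor did any other of the 8 classes. On balance its members moved down (limma's fry, unadjusted p = 0.006417). The share of counts on annotated non-coding loci was 5.43% ± 0.204 in untreated and 4.07% ± 0.163 in IL-4 libraries (exact permutation p = 0.02857, adjusted over 10 shares 0.04081). The 2 most abundant loci of the class, on chromosomes 14 and 19, held 92.1% of this difference, with 2.93% ± 0.220 and 1.67% ± 0.0959 of the counts. The other 3349 loci held 2.50% ± 0.129 and 2.39% ± 0.169 (exact permutation p = 0.4). Among them the chromosome 17 locus (39979941 to 39985777) went the other way, from 0.811% to 0.980% of the counts. It offsets falls among the rest, so neither the 92.1% nor this p shows that the rest held their share. Protein-coding loci took 90.8% ± 0.169 and 92.5% ± 0.205, a rise of 1.658 percentage points. The protein-coding locus on chromosome 9 (7344397 to 7369499) alone went from 0.105% to 2.45% of the counts. That gain exceeds the rise of the class, so the other protein-coding loci together did not gain share. Such a gain also lowers the shares of all other loci by itself. The class share was lower and the protein-coding share higher with IL-4 in all 4 replicate pairs, for which the smallest two-sided exact p is 0.125, so a test within pairs cannot pass 0.05. Of 36 small non-coding loci, 3 rose and 3 fell.

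The largest fitted fall in this class was XLOC_004286, a 2-exon locus on chromosome 11 (43182032 to 43199202). It fell from 128 ± 9.29 to 1.62 ± 0.80 CPM, 72.9-fold lower (edgeR, adjusted p = 7.156e-09). A 3-exon non-coding locus on the X chromosome (93434069 to 93441587) fell from 369 ± 72.8 to 28.8 ± 12.4 CPM, 11.8-fold lower. Non-coding loci on chromosomes 2 (166272707 to 166285934), 12 (33796576 to 33832462), 16 (97757671 to 97782800) and 2 (84328645 to 84408703) fell 9.20-fold, 8.82-fold, 7.52-fold and 5.73-fold. The rises, ordered by fitted values, began with a locus on chromosome 9 (122481419 to 122592880), from 1 to 1428 counts with a ratio of 1344 and an interval of 240.9 to 53140. Its only untreated count was in replicate 3, and without that library it was at least 343.2-fold higher. The next was on chromosome 10 (84683687 to 84729137), from 0 to 470 counts, at least 147.5-fold higher. A 10-exon non-coding locus on chromosome 3 (31165239 to 31248338) rose from 0.0685 ± 0.0635 to 19.3 ± 2.40 CPM, 272.9-fold, and a 3-exon locus on chromosome 16 (11778475 to 11781593) from 0.177 ± 0.143 to 32.3 ± 6.92 CPM, 195.4-fold, so both exceeded the bound of the chromosome 10 locus. Without untreated replicate 2 the ratio of the former was 462.4 (158 to 2244), and without untreated replicate 3 the latter rose 309.6-fold. Non-coding loci on chromosome 16 (51979649 to 51987413) and chromosome 3 (64936882 to 65106607) rose 39.3-fold and 19.2-fold. The 2 most abundant non-coding loci, chosen after their values were seen, lie on chromosomes 14 (51427122 to 51427446) and 19 (5793730 to 5805148). They went from 16617 ± 2190 to 10015 ± 1155 CPM and from 12653 ± 2644 to 6724 ± 390 CPM, with log2 fold changes of -0.63 (SE 0.12) and -0.80 (SE 0.14), but neither passed against a change of 1.5-fold (edgeR's glmTreat, adjusted p = 0.598 and 0.1102). The next, on chromosome 17 (39979941 to 39985777), went from 8112 ± 876 to 9803 ± 1936 CPM (edgeR, adjusted p = 0.03596). That call was lost without untreated replicate 1, 2 or 4 or IL-4 replicate 2 or 3 (adjusted p = 0.05555 to 0.09209), without both replicate 4 libraries (0.08067) and with glmTreat.

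Loci without any reference transcript also changed. Of 2250 such loci, 486 rose and 490 fell, against 249 and 224 with glmTreat, and 306 fell with the stricter filter on counts. Among 309 intergenic loci with several exons, 102 rose and 89 fell. Among 1779 intergenic loci with a single exon, 342 rose and 345 fell. Of 131 antisense loci, 32 rose and 45 fell. Counts fell short of FPKM where exons are shared, so counts of a locus and its antisense partner may lack reads there. Without knowledge of strand, whose reads the others are is uncertain.

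At the level of isoforms, 6712 of 17500 tested transcripts changed, 3472 up and 3240 down (limma, adjusted p under 0.05). Which direction had more calls depended on the processing. With quantile normalization 3258 rose and 3459 fell, and without a filter on FPKM 4259 rose and 4430 fell. With FPKM of at least 5 required, 4185 of 8152 changed, and 1730 of these fell. Of 1031 unannotated transcripts 329 changed, 209 up and 120 down. Adjusted over these alone, 307 changed. Without both replicate 4 libraries, which carried reads of chromosome Y, 2268 of 15873 tested isoforms rose and 217 of 955 unannotated transcripts changed. The filter still asked for FPKM of at least 1 in 4 libraries, so isoforms at that level in a single group dropped out. The largest rise among unannotated multi-exon transcripts was a 2-exon intergenic transcript on chromosome 3 (122080026 to 122095587), from 0.0212 ± 0.0256 to 18.2 ± 0.508 FPKM, a log2 fold change of 7.26 (SE 0.17, limma, adjusted p = 3.432e-08), and 9.54 and 4.23 with pseudocounts of 0.01 and 1. A pair of antisense isoforms on chromosome 18, both starting at 62904107, rose from 0.104 ± 0.0687 to 5.45 ± 2.06 FPKM and from 0.0476 ± 0.0415 to 2.54 ± 0.875 FPKM. An antisense transcript on chromosome 14 (51868686 to 51884264) was listed at 0 in all 4 untreated libraries and at 1.66 ± 0.192 FPKM with IL-4. It overlaps an opposite-strand locus with an isoform that went from 0 to 2237 FPKM, and 54.4% of the exonic nt of its own locus are shared, so whose reads these are is uncertain. A 267-nt transcript on chromosome 2 (44975276 to 44977168) was listed at 0 in 3 untreated libraries and at 2.83 ± 1.69 FPKM with IL-4, a log2 fold change of 4.02, 4.66 without untreated replicate 3, and 6.50 and 1.68 with pseudocounts of 0.01 and 1. The largest fitted falls were on chromosome 5 (67841679 to 67848703), from 5.81 ± 1.19 to 0.548 ± 0.690 FPKM, with a log2 fold change of -4.10, -4.83 without IL-4 replicate 1 and -3.51 without IL-4 replicate 2 or 3, and on chromosome 13 (44562439 to 44575704), from 8.68 ± 3.06 to 0.735 ± 0.274 FPKM. With pseudocounts of 0.01 and 1 the former was -5.80 and -2.23, and with a pseudocount of 1 the latter, at -2.44, was the larger fall. Further falls were on chromosome 16 (91366855 to 91367477), from 3.31 ± 0.850 to 0.377 ± 0.225 FPKM, on chromosome 6 (82951639 to 82955126), from 3.39 ± 0.570 to 0.361 ± 0.108 FPKM, and on chromosome 17 (84435105 to 84526639), from 1.45 ± 0.0808 to 0.145 ± 0.0648 FPKM. All exonic nt of the loci on chromosomes 16 and 6 are shared with another locus, and both had 0 counts.

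Isoforms of a locus were called as moving apart at 647 of 4105 tested loci (limma diffSplice). In simulated data this test gave 39 false calls among 3770 loci, more than the threshold allows, so the 647 may hold false calls. The ratio of each isoform to the rest of its locus was added for that reason, after the data were seen. It called 515 loci, and 439 were called by both. At 2 of the 647 all isoforms were listed at 0 in every library of a group, so their call rests on the pseudocount. At 15 called loci the summed mean FPKM was under 1 in a group. The pseudocount can also weigh on calls where single isoforms lie far under 0.1 FPKM in a group. Of 4064 loci with a summed FPKM of at least 1 in both groups, 632 were called. At 184 called loci no isoform's share moved by 5 percentage points. DiffSplice called 328 of 3613 loci without both replicate 4 libraries, where fewer isoforms passed the filter. It called 285 of 1201 with FPKM of at least 5 and 2477 of 12339 without a filter on FPKM. The share called was 33.41% among 425 loci that join non-overlapping reference transcripts and 13.72% among the others (Fisher's exact test, p = 8.997e-22). Loci measured in the same libraries are not independent replicates, and the number of isoforms per locus was not adjusted for. At the locus on chromosome 5 (141200081 to 141237413) an 8-exon reference isoform made up 61.6% ± 5.07 of the summed FPKM with IL-4, at 9.09 FPKM, and was listed near 0 in untreated libraries, while a 7-exon assembled isoform starting at 141211631 went from 39.6% ± 7.88 to 6.25% ± 2.00. At the locus on chromosome 9 (108890335 to 108934813) the isoform spanning the whole locus rose to 35.8% ± 7.74, and a 6-exon isoform starting at 108919395 went from 54.2% ± 5.91 to 16.4% ± 4.05. On chromosome 11 (69941090 to 69984336) a 10-exon reference isoform ending at 69951044 rose from 7.89% ± 1.63 to 68.2% ± 1.01 of a locus that joins 2 groups of reference transcripts. The locus on chromosome 7 (142810632 to 142908093) also joins 2 such groups, and its 14-exon reference isoform fell from 50.4% ± 5.98 to 12.9% ± 2.83. At the joined chromosome 3 locus starting at 105945169, which had the smallest Simes p, the main reference isoform held 96.4% ± 0.724 and 93.9% ± 0.0436. Its other isoforms had untreated means of at most 0.0186 FPKM, under the pseudocount of 0.1. That limits their fitted folds, so this call rests in part on the pseudocount. On chromosome 14 (51868686 to 51876313) both isoforms were listed at 0 in untreated libraries, so no untreated share exists, and the 2-exon reference isoform reached 2237 FPKM with IL-4. That locus shares 89.3% of its exonic nt with another locus and had 6 counts over all libraries.

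**Figure D3:**
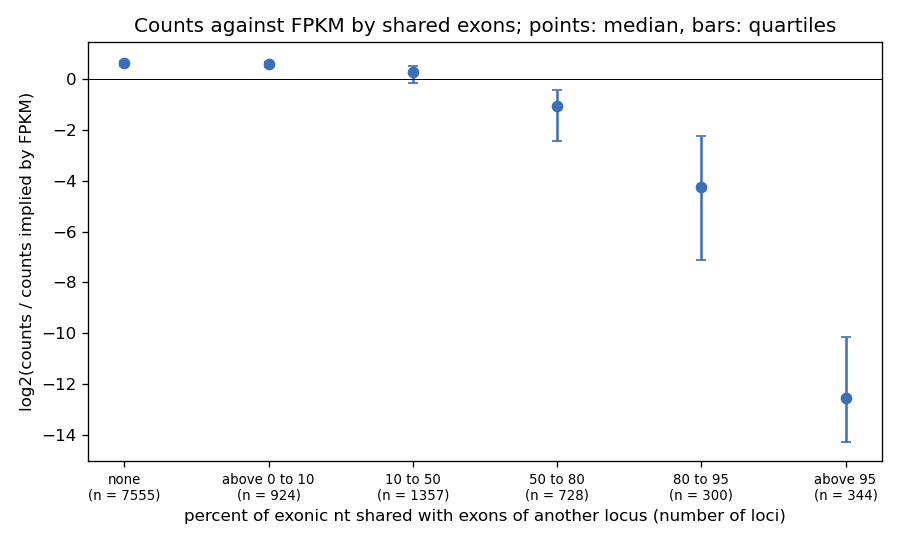
For loci whose FPKM imply over 400 counts, the log2 ratio of deposited to implied counts (vertical axis) by the percent of exonic nt shared with another locus (horizontal axis). Points are medians and bars run from the lower to the upper quartile over the loci of a bin. The median went from 0.65 without sharing to -12.54 above 95% sharing.

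Counts and FPKM gave like fold changes at most loci tested in counts. Across 13761 loci, which are not independent replicates, the log2 fold changes of counts and of summed FPKM correlated at 0.9261 (Pearson) and 0.9566 (Spearman). Of 2211 called loci with a change of 2-fold or more, 99.55% had the same sign in both. The Pearson correlation was 0.9346 at loci without shared exons and 0.8352 at loci that share over 50% of their exonic nt. Of 11208 loci whose FPKM imply over 400 counts, 775 had counts over 16-fold below the implied number, and 331 of these held an isoform that changed with IL-4. Only 212 of the 775 were tested in counts, so most of them enter neither the correlations nor the counts of changed loci. Both loci of the mitochondrial chromosome, on opposite strands, had 0 counts in all libraries, while a transcript there reached a mean of 2526 FPKM.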

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

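All tests in this part on chromosome Y and on lost counts were chosen after the results were seen. A library was set apart where its gap to the nearest other library of its group, divided by the range of the group, exceeded Dixon's critical value at the 95% level. This was examined in 179 groups of 4 libraries, leaving out groups at or under 3 counts or under 0.1 FPKM in every library, a limit set after the values were seen, and 14 had such a library where chance gives about 1 in 20. Of the 14, 6 were in replicate 4.

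Reads of chromosome Y occurred almost only in replicate 4 of each group. Chromosome Y levels were 242 CPM in untreated replicate 4, against 0 to 0.303 in the others (gap ratio 0.9987), and 204 CPM in IL-4 replicate 4, against 0.0360 to 0.125 in the others (gap ratio 0.9996). They fell on 4 loci. A single wrong label in either group is argued against, since the IL-4 to untreated ratio of the level in replicate 4 was 0.8427. Reads carried over from another of the 8 libraries are argued against as well, since the highest level elsewhere was 0.1485% of the lower replicate 4 value. Cells of a male animal, alone or mixed with others, in both replicate 4 cultures may be the source and stay open, as does a pair of outside samples; the labels used here give no sex, and no biological explanation was tested.

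Counts far below the number implied by FPKM were a second pattern. The median log2 ratio was lower by more than 13 where over 95% of the exonic nt were shared with another locus than where none were (difference -13.19), a value that a counter discarding reads over exons of several loci would give. Short transcripts with inflated FPKM are argued against for lost loci with shared exons, of which 1.161% had under 300 exonic nt, but not for lost loci without shared exons, of which 51.16% did. Why the 172 lost loci without sharing have low counts stays open. No biological explanation was tested.

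The other libraries set apart were these. The chromosome 16 locus starting at 48842665 had 394 CPM in IL-4 replicate 4 and 564 to 591 in the others (0.8616). The chromosome 18 locus starting at 60535683 had 0.148 CPM in IL-4 replicate 4 and 0 in the others (gap ratio 1). The chromosome 16 locus starting at 11778475 had 0.390 CPM in untreated replicate 3 and 0.0807 to 0.125 in the others (0.8561). The chromosome 12 locus starting at 33796576 had 3.79 CPM in untreated replicate 1 and 5.13 to 5.33 in the others (0.8721). The abundant chromosome 14 locus starting at 63740803 had 19147 CPM in IL-4 replicate 4 and 16096 to 16252 in the others (0.9489). Untreated replicate 1 had 18226 CPM, against 13826 to 14415, at the chromosome 7 locus starting at 149561821 (0.8662), and 638 CPM, against 1156 to 1222, at the chromosome 9 locus starting at 7344397 (0.8869). The chromosome 4 locus starting at 43505657 had 8356 CPM in IL-4 replicate 1 and 4716 to 5173 in the others (0.8743). Among isoforms, that on chromosome 2 starting at 44975276 had 0.502 FPKM in untreated replicate 3 and was listed at 0 in the others (gap ratio 1). A 12-exon isoform of the chromosome 3 locus starting at 105945169 had 16.4 FPKM in IL-4 replicate 3 and 14.1 to 14.5 in the others (0.8372). An assembled isoform on chromosome 5 starting at 141211454 had 3.40 FPKM in IL-4 replicate 4 and 2.37 to 2.47 in the others (0.9029). A 6-exon isoform of the chromosome 7 locus starting at 142810632 had 0.939 FPKM in untreated replicate 2 and 0.823 to 0.834 in the others (0.9061).

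Of 35 splits of the 8 libraries into 4 and 4, only 1, the real split, gave as many calls. That is a share under 0.05 for each count of calls if every split is taken as equally likely. The highest other split called 0 loci against 7127, 0 non-coding loci against 272, 7 isoforms against 6712, 0 unannotated transcripts against 329 and 9 loci of isoform use against 647. The other splits mix libraries of both groups on each side, which puts the difference between the groups into their spread. If the numbers pair the libraries, as was taken above, only 8 splits part all pairs, too few for a share under 0.05. The splits then cannot exclude chance. The 7 others among the 8 called at most 0, 0, 1, 0 and 7.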

How the results depend on the processing

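The alternatives without both replicate 4 libraries, with loci of low exon sharing, with isoform ratios, with FPKM of at least 1 in both groups and without the 2 most abundant non-coding loci were chosen after the data were seen. For the loci, isoforms and loci of isoform use named by rule, all 780 values under the alternatives stayed on the same side of the threshold. The alternative of low exon sharing only took a subset of the main fit, so its locus values repeat the main ones. The rule took the largest changes past the threshold or the smallest Simes p, so that these stayed called was likely from the start. Fold changes also kept their direction, though some sizes moved. No direction was checked for the 85 values of isoform use. Isoforms that no longer passed the filter on FPKM were not recomputed. That filter still asked for 4 libraries when some were left out. Isoforms that reached the minimum only in the reduced group therefore dropped out. The differences in 3 shares of counts kept their direction, and the non-coding one shrank to -0.1076 percentage points without its 2 most abundant loci. The loci left then include the chromosome 17 locus starting at 39979941, whose share was higher with IL-4. No alternative left out the chromosome 9 locus starting at 7344397, whose gain in share exceeded that of the protein-coding class. For the most abundant loci 228 values, some of them such repeats of the main fit, kept their side of the threshold. A further 38 passed no longer and 3 passed only then, the latter at the chromosome 14 and chromosome 4 loci. Requiring a change beyond 1.5-fold by edgeR's glmTreat left 2467 loci (1241 up, 1226 down) and 111 non-coding ones (39 up, 72 down). Without a filter on counts 127 non-coding loci rose and 214 fell. Without a filter on FPKM 941 unannotated transcripts and 2477 loci of isoform use were called, and with FPKM of at least 5, where fewer isoforms are tested, 4185 isoforms (1730 down) and 285 loci of isoform use. Without both replicate 4 libraries, which leaves fewer samples, 2268 isoforms rose, 217 unannotated transcripts changed and 328 loci changed isoform use. Then 15873 isoforms passed the filter on FPKM, against 17500 with all libraries. Apart from fewer features or samples, the cause was not tested. With the replicate block 3915 loci rose and 4050 fell, with 299 non-coding loci, 6767 isoforms, 328 unannotated transcripts and 710 loci of isoform use changed, and apart from the abundant loci it changed no call of a named locus. Leaving out each library gave 6537 to 7696 loci, 244 to 304 non-coding loci, 5317 to 6517 isoforms, 257 to 332 unannotated transcripts and 452 to 699 loci of isoform use. DESeq2 called 4087 up and 3519 down, and RLE factors 3711 up and 3460 down. Loci sharing at most 10% of their exonic nt made up 5891 of the calls. Fewer loci fell or rose under glmTreat by its construction: 952 protein-coding loci rose and 927 fell, 249 unannotated loci rose and 224 fell, and with the stricter filter 306 unannotated loci fell. The tests of the fixed gene lists, with all their alternatives, were not run because no list symbol matched an ID. Depth limits folds against a group at 0 counts, which are bounds, and against 1 to 3 counts, which have wide intervals.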

Other observations

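The tests of neighbouring loci were set before their results were seen, and their repeats on ranks and the test of runs after.

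Unannotated single-exon loci moved with the nearest annotated locus. Within 5 kb downstream of an annotated locus the log2 fold changes of 195 pairs correlated at 0.8363 (95% bootstrap interval 0.6918 to 0.907), and upstream those of 326 pairs at 0.5419 (0.3975 to 0.6711). At over 50 kb, 575 pairs gave 0.0534. These are correlations across loci, which are not independent replicates. The downstream value exceeded the upstream one by 0.2944 (0.1067 to 0.4519). On ranks the values were 0.6403 and 0.4844, and the difference was smaller, 0.1558 with an interval of 0.01098 to 0.299 that nearly reaches 0. Both are consistent with transcripts that run past their annotated end as a source of some of these loci, a hypothesis. Where both members were called, 88.1% of downstream and 87.06% of upstream pairs moved the same way, and the correlation at 5 to 20 kb was 0.7054, so such extension may not be the whole cause. A regional change shared by any neighbours is argued against as the whole cause, since adjacent annotated loci within 5 kb correlated at 0.3756, lower by 0.291 (0.147 to 0.4255), and on ranks by 0.282 (0.1979 to 0.361).

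Protein-coding loci that changed 2-fold or more in the same direction followed each other in 15 runs of at least 4, of which 10 fell and 5 rose. Runs were taken in the order of tested protein-coding loci. Other loci between them were passed over, with no limit on distance. A run on chromosome 9 thus spans 92331532 to 95130953. In 10000 shuffles of the loci the median number of runs was 0 and the highest 5 (permutation p = 0.0001, the smallest they can give). The longest runs held 7 loci that fell on chromosome 19 (34625184 to 34954010) and 7 that fell on chromosome 5 (121098264 to 121357554). A run of 6 loci that rose lies on chromosome 17 (37616992 to 37776168), with up to 89.76% of the exonic nt of a locus shared with another locus. In 9 runs no locus shared over 10% of its exonic nt. Reads shared between similar neighbouring genes may contribute to such runs and were not tested, because sequences were not used here.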
